A study of Mus musculus with 24 samples.

How the data were processed

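RNA of 4 sorted mouse progenitor populations, WT and Ikaros-null, was hybridised to 24 Affymetrix one-colour arrays, 3 per population and genotype. The titles call the arrays of a group biological replicates, and nothing says whether each came from 1 animal or a pool. Per the labels, total RNA was extracted with Trizol and biotinylated cRNA was made from 6 ug. The GFP reporter line is C57BL/6 x C3H and the Ikaros-null line C57BL/6 x 129SV. Per the submitters' processing notes, the authors processed the arrays with RMA, and the deposited values are log2 signal. The RMA version is not given in the sources used here. Values ranged from 3.33 to 14.5, and the number of arrays per group limits the precision.

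The table has 45101 probe sets. The 64 control probe sets were left out, as were 932 probe sets with several gene symbols and 9160 with none. Of the 34945 with 1 symbol, 34741 matched the reference gene table by Entrez ID, and 0 symbols were updated. For each gene the probe set with the highest mean over all arrays was kept, which gave 18193 genes. Gene coordinates are from the reference table, whose build is GRCm38.p6, since the array files carry none. The columns of per-sample values were all used.

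Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) in 1 fit of 8 group means over 24 arrays, with 16 residual and 3.27 prior degrees of freedom. Standard errors are the moderated ones of limma, two-sided p-values were adjusted by Benjamini and Hochberg over genes within a comparison, and the threshold was 0.05. Exact permutation tests of 3 against 3 arrays cannot go below 0.1. The comparisons were KO against WT in each population, 4 between WT populations, 4 interaction contrasts and the mean of the 4 KO effects. The p-values measure the spread between arrays. Y-linked and Xist RNA were both present on many arrays, which points to pools of both sexes.

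Gene lists (25) were written before the data were examined, as were the comparisons, tests and most alternatives. They cover stem cell, early lymphoid, B lineage, T and NK, granulocyte and monocyte progenitor, mature neutrophil, macrophage, dendritic, MHC class II, erythroid, heme synthesis, megakaryocyte, mast and basophil, eosinophil, plasma cell, stroma and endothelium, proliferation, Notch, interferon response, immediate early, Ikaros complex, Hox, ribosomal protein and sex-linked genes and neighbours of Ikzf1. All genes within 10 Mb of Ikzf1 made a further list of 129. Lists were tested with camera, with the preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. Members were also counted with p-values adjusted over the list alone. Signatures of 150 genes (75 and 300 as alternatives) were taken from WT comparisons and tested in KO comparisons that share no arrays. Overlaps of calls were set beside the product of the call rates.

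Named genes were chosen by a fixed rule. It took the 8 largest rises and falls among called genes whose arrays do not overlap in each KO and WT comparison, and 4 each way in interactions and the mean. It added up to 2 called members of each list with the smallest adjusted p, and a panel of 26 genes, of which 24 are on the array. Clone symbols were passed over. List members and panel genes could be left out where a list is given as a count. Further list members, recurring genes and 1700042O10Rik were named after their values were seen.

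The replicate numbers in the titles were checked for pairing by correlating the residuals of same-numbered arrays across genes. They were taken to pair a comparison when every pair had r above 0.1. This held for KO against WT in LSK GFPneg-lo (lowest r = 0.276), LK GFPneg (0.359) and LK GFPhi (0.175), for the 4 WT comparisons (0.414, 0.550, 0.171 and 0.582) and for the LK interaction (0.169). It did not hold for KO against WT in LSK GFPhi (0.0238), the other 3 interactions or the mean effect (-0.0891). Eif2s3y on KO LK GFPhi replicate 3 (7.74) differed from the other KO arrays numbered 3 (4.01 to 4.14), so the block may join different mice there.

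The alternatives were a fit of the compared groups alone, replicate number as a block, the dimmest 40% of probe sets left out (12878 genes kept), probe sets ending in _x_at and _s_at left out (17903 genes kept), trend and robust eBayes, array weights, median centring, a further quantile normalization, a 2-fold minimum, and each array left out in turn. Eif2s3y level as a covariate was added after the sex-linked genes were seen. The steps were tested on simulated data with 200 changed genes among 18193. For changes of 0.5, 1 and 2 log2 units, the 8 comparisons of 2 groups recovered 29.9 to 47.8%, 70.1 to 86.6% and 95.5 to 100%, with 2.74 to 6.96% false calls. Interactions recovered 2.99 to 16.4%, 59.7 to 68.7% and 93.9 to 98.5%. A list shifted by 0.5 was found in 13 of 13 comparisons, and 1 of 325 unchanged lists was called. The simulated noise was independent between genes and between arrays. These rates therefore do not cover the correlation between genes of a list or between same-numbered arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.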

Results

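RNA from 4 sorted blood progenitor populations of wild-type (WT) mice and of mice lacking Ikaros (KO) was measured on 24 Affymetrix mouse arrays, 3 for each population and genotype. Ikaros, encoded by Ikzf1, is a zinc finger transcription factor of blood cells. The cells were sorted as LSK (in the field's usage lineage-negative, Sca-1-positive and Kit-positive) or LK (lineage-negative, Kit-positive) and by a GFP reporter built on Ikaros regulatory sequence. The labels name LSK GFPneg-lo as HSC (stem cells), LSK GFPhi as LMPP (lymphoid-primed multipotent progenitors), LK GFPneg as MEP (megakaryocyte and erythroid progenitors) and LK GFPhi as GMP (granulocyte and monocyte progenitors). Arrays of 1 group correlated at r = 0.979 to 0.996 across genes, which are not independent replicates. The number of arrays limits the precision of every value. A value after a gene is the log2 difference, first group minus second, with its limma standard error (n = 3 arrays per group), and a gene was called where its adjusted p fell below 0.05.

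The comparisons of KO with WT ask what differs with loss of Ikaros in each population, and Ikzf1 itself shows that the genotypes differ. It is no control for strain or sex. The Ikaros-null and GFP reporter lines have different strain backgrounds, and no group separates strain from genotype. Y-linked RNA was also lower on part of the KO arrays, as given below. Ikzf1 (chromosome 11, 11684962 to 11772930) had WT means of 11.15 ± 0.19 (SD, n = 3) in LSK GFPneg-lo, 11.57 ± 0.15 in LSK GFPhi, 11.84 ± 0.13 in LK GFPneg and 11.58 ± 0.13 in LK GFPhi. In KO cells the means were 7.52 ± 0.43, 7.43 ± 0.66, 8.40 ± 0.81 and 7.24 ± 0.67. The differences of -3.63, -4.15, -3.45 and -4.34 (standard error 0.36 each) were called in all 4 populations. A second probe set of the gene stayed between 6.10 and 6.39 in every group, so it tests nothing. Sex-linked genes also differed between arrays. The Y-linked gene Eif2s3y lay between 7.88 and 10.4 in the 12 WT arrays. It was 4.14, 7.99 and 4.01 in KO LSK GFPneg-lo replicates 1, 2 and 3. Replicates 1, 2 and 3 gave 3.99, 7.20 and 4.13 in KO LSK GFPhi, 4.08, 8.33 and 4.14 in KO LK GFPneg, and 4.01, 7.58 and 7.74 in KO LK GFPhi. It is therefore not known whether KO LK GFPhi replicate 3 came from the same mice as the other KO arrays numbered 3. Xist, which is transcribed from the inactive X chromosome, was between 11.97 and 13.4 on every array. The median of the 4 measured sex-linked genes was -1.56, -1.48, -1.22 and -1.40 in the 4 populations, with 0 of 4 called in each (3, 2, 2 and 1 lower adjusted over the list alone).

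**Figure D1:**
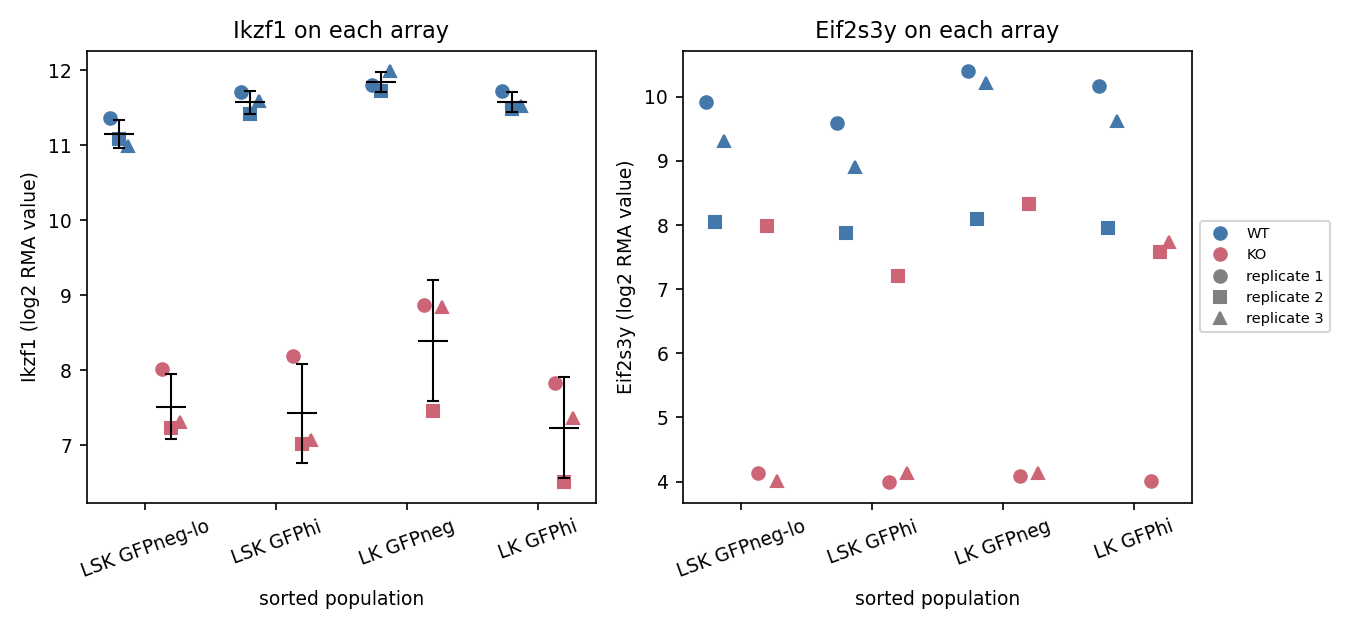
Ikzf1 (left) and Eif2s3y (right) on each of the 24 arrays, in log2 units, by population, WT blue and KO red, with circle, square and triangle for replicates 1, 2 and 3 and bars for the mean ± SD of Ikzf1. Ikzf1 group means were 11.15 to 11.84 in WT and 7.24 to 8.40 in KO, and Eif2s3y was near 4 in 7 of the 12 KO arrays.

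In the LSK GFPneg-lo population, the largest rise in KO cells was in Cdh5 (4.93 ± 0.13, adjusted p = 2.97e-15), which encodes the endothelial adhesion protein VE-cadherin. Nrep (3.84 ± 0.37), the glutathione transferase gene Gstm2 (3.52 ± 0.16), Clu (3.10 ± 0.21), which encodes the secreted chaperone clusterin, Dlk1 (3.09 ± 0.26) and the surface glycoprotein gene Thy1 (2.94 ± 0.29) rose as well. Ltb (-2.15 ± 0.34), which encodes the lymphoid cytokine lymphotoxin beta, Dmxl2 (-2.08 ± 0.20), Klhl4 (-1.94 ± 0.24) and the growth suppressor gene Ndn (-1.92 ± 0.30) fell. Of 21 measured megakaryocyte genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone). They included the adhesion receptor gene Selp (2.41 ± 0.28) and the thrombin receptor family gene F2rl2 (1.84 ± 0.20). This list passed camera with its preset correlation (adjusted p = 2.43e-06), with adjusted p = 0.103 with an estimated correlation. Of 21 granulocyte and monocyte progenitor genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 7.76e-05, and 0.103 with an estimated correlation). They included the colony stimulating factor receptor gene Csf1r (1.46 ± 0.24) and Cebpd (1.37 ± 0.21), both of which lost the call in a fit of these 6 arrays alone. Of 19 interferon response genes, 0 rose and 4 fell (0 and 7 adjusted over the list alone), among them Ifit1 (-1.67 ± 0.30) and Rtp4 (-1.48 ± 0.26). The interferon list had adjusted p = 1.61e-15, and 0.103 with an estimated correlation. Of 31 proliferation genes, 1 rose (10 adjusted over the list alone; median 0.46, adjusted p = 1.11e-10, and 0.103 with an estimated correlation). Mki67 was 0.41 ± 0.26 and was not called.

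In the same LSK GFPneg-lo comparison, 6 of 23 stem cell genes rose and 1 fell (7 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.638). Fgd5 (1.19 ± 0.26), a marker of stem cells, rose, while Ndn fell, and Procr (0.12 ± 0.27) and Mecom (-0.50 ± 0.25) were not called. Of 19 early lymphoid genes, 0 rose and 3 fell (2 and 5 adjusted over the list alone; adjusted p = 0.0063, and 0.204 with an estimated correlation). Flt3 was -1.07 ± 0.29 (adjusted p = 0.0604) and Il7r 0.55 ± 0.26, neither of them called. Of 9 MHC class II genes 2 fell (3 adjusted over the list alone; adjusted p = 6.96e-06, and 0.103 with an estimated correlation). Of 12 stroma and endothelium genes 2 rose, Cdh5 being the larger (3 adjusted over the list alone; adjusted p = 0.000289, and 0.103 with an estimated correlation). The basophil gene Mcpt8 (1.81 ± 0.26) was the 1 of 12 mast and basophil genes that rose (3 adjusted over the list alone; adjusted p = 0.00445, and 0.204 with an estimated correlation). The macrophage list had 2 of 15 genes higher (4 adjusted over the list alone; adjusted p = 0.0475, 0.0896 with the replicate block and 0.343 with an estimated correlation). Heme synthesis (0 of 10 called, 0 adjusted over the list alone; adjusted p = 0.0386) and immediate early genes (0 of 18 called, 0 adjusted over the list alone; adjusted p = 0.021) had 0.231 and 0.556 with an estimated correlation. The mean of the immediate early genes was 9.94, 8.61 and 8.69 on KO replicates 1, 2 and 3, and 9.41 to 9.49 on the WT arrays, so KO replicate 1 stood apart. It was the highest KO array for these genes in all 4 populations. Without KO replicate 2 or 3 of LSK GFPneg-lo the immediate early list did not pass (adjusted p = 0.482 and 0.404), and without replicate 1 it passed. The sex-linked list had adjusted p = 0.00459, and 0.103 with an estimated correlation. The 14 other lists did not pass (adjusted p 0.19 to 0.963). Limma called 389 of 18193 genes, 229 higher and 160 lower in KO, of which 172 differed at least 2-fold. With replicate number as a block 844 genes passed, and 1120 with array weights. In a fit of these 6 arrays 199 passed, with Eif2s3y as a covariate 210, without WT replicate 1 232 and without KO replicate 3 244.

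In the LSK GFPhi population, genes of early lymphoid cells fell in KO cells and genes of stem cells rose. Of 19 early lymphoid genes, 0 rose and 13 fell (0 and 13 adjusted over the list alone; median -0.95, adjusted p = 7.26e-19, and 0.000658 with an estimated correlation). They included Rag1 (-0.88 ± 0.12, adjusted p = 5.02e-05), which encodes part of the antigen receptor recombinase, the cytokine receptor gene Flt3 (-1.34 ± 0.29) and the immunoglobulin heavy chain gene Ighm (-2.60 ± 0.36). The interleukin 7 receptor gene Il7r (-1.22 ± 0.26) fell too, but lost the call in a fit of these 6 arrays alone. Of 23 stem cell genes, 8 rose and 1, Ndn, fell (12 and 2 adjusted over the list alone; median 0.60, adjusted p = 8.39e-09, and 0.0129 with an estimated correlation). Fgd5 (3.90 ± 0.26), the endothelial receptor gene Tie1 (2.82 ± 0.25), the protein C receptor gene Procr (2.48 ± 0.27) and Vwf (3.20 ± 0.52) were among those that rose. Several stem cell genes that rose, Tie1, Vwf, Tek and Esam among them, are also known from endothelium. Mecom (-0.28 ± 0.25) and Gata2 (0.60 ± 0.18, adjusted p = 0.0646) were not called.

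Plasma cell genes fell in KO LSK GFPhi cells: 4 of 8 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.33, adjusted p = 3.22e-06, and 0.00147 with an estimated correlation). They included Jchain (-4.17 ± 0.44), which encodes the joining chain of secreted antibody, and the syndecan gene Sdc1 (-2.63 ± 0.26). The germ cell helicase gene Ddx4 (-4.97 ± 0.41), the immunoglobulin gene Igkv8-30 (-2.96 ± 0.31) and Cmah (-2.87 ± 0.24), which makes a form of sialic acid, fell as well. Of 21 granulocyte and monocyte progenitor genes, 6 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.87, adjusted p = 1.84e-09, and 0.0171 with an estimated correlation). Cebpd (1.57 ± 0.21) and Csf1r (1.27 ± 0.24) rose, and Mpo (0.18 ± 0.31), which encodes the granule enzyme myeloperoxidase, was not called. Of 19 interferon response genes, 9 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.84, adjusted p = 3.86e-17, 0.0364 with an estimated correlation and 0.0585 when the block was added to that). Rtp4 (-1.74 ± 0.26) was among them. The interferon list had means of 8.93, 8.84 and 9.78 on WT LSK GFPhi replicates 1, 2 and 3 and of 8.15 to 8.30 on the KO arrays, so WT replicate 3 stood apart. Without WT LSK GFPhi replicate 3 its median was -0.54 and it still passed. Of 21 megakaryocyte genes 5 rose (5 adjusted over the list alone), including Selp (3.84 ± 0.28), Itgb3 (2.25 ± 0.22) and Itga2b (1.72 ± 0.24). The megakaryocyte list had adjusted p = 1.11e-07, and 0.0774 with an estimated correlation.

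Large rises in the LSK GFPhi population were in the clone gene 1700042O10Rik (4.01), Cdh5 (5.32 ± 0.13), Thy1 (4.71 ± 0.29), Selenom (4.53 ± 0.29), the mannose receptor gene Mrc1 (4.14 ± 0.39), the lipid carrier gene Apoe (3.98 ± 0.38) and Pmaip1 (3.93 ± 0.27), which encodes an inducer of cell death. Tmem204 (4.72 ± 0.35) also rose, but its other probe set gave 0.46. The granule protein gene Lcn2 (3.73 ± 0.30), the basophil gene Mcpt8 (2.64 ± 0.26) and the lipopolysaccharide receptor gene Cd14 (2.13 ± 0.22) rose. The antigen loading gene H2-Ob (-2.42 ± 0.25) and the integrin gene Itgax (-0.54 ± 0.10) fell. The macrophage list had 3 of 15 genes higher (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.00348, and 0.148 with an estimated correlation). The mast list had 3 of 12 higher (4 adjusted over the list alone; adjusted p = 0.0027, and 0.148 with an estimated correlation). The dendritic list had 4 of 12 lower (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.00191, and 0.103 with an estimated correlation). Its 4 were Itgax, Flt3, Ccr7 and Irf4, of which Flt3 and Ccr7 are also in the early lymphoid list. B lineage (0 higher and 1 lower of 18, 1 and 4 adjusted over the list alone), stroma and endothelium (2 and 1 of 12, 2 and 1 adjusted over the list alone), proliferation (1 and 0 of 31, 1 and 0 adjusted over the list alone) and sex-linked genes had adjusted p = 0.0305, 0.0186, 0.0305 and 0.0184. With an estimated correlation these became 0.416, 0.184, 0.636 and 0.146. The 13 other lists did not pass (adjusted p 0.095 to 0.984). Limma called 837 genes, 530 higher and 307 lower in KO, and 384 of them differed at least 2-fold. With array weights 1288 genes passed, and 499 with Eif2s3y as a covariate.

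In the LK GFPhi population, early lymphoid genes fell in KO cells while some genes of several other lineages rose. Of 19 early lymphoid genes, 1 rose and 11 fell (1 and 13 adjusted over the list alone; median -0.98, adjusted p = 2.79e-13, and 0.00427 with an estimated correlation). Il7r (-2.78 ± 0.26), Rag1 (-1.69 ± 0.12) and the Notch receptor gene Notch1 (-1.42 ± 0.28) fell, as did Dntt (-3.45 ± 0.48), which encodes the polymerase that adds bases to antigen receptor joints, and Flt3 (-1.68 ± 0.29). Dntt and Flt3 lost the call in a fit of these 6 arrays alone. The member that rose was Cnr2 (adjusted p = 0.0229), which encodes a cannabinoid receptor of B cells. Of 23 stem cell genes, 10 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.46, adjusted p = 8.71e-07, 0.0404 with an estimated correlation and 0.133 when the block was added to that). Fgd5 (4.77 ± 0.26), Procr (2.62 ± 0.27) and Gata2 (1.39 ± 0.18), which encodes a transcription factor of stem and mast cells, rose. Of 16 mature neutrophil genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.45, adjusted p = 2.63e-05, 0.0404 with an estimated correlation, 0.0924 when the block was added to that and 0.0979 without KO replicate 1). Lcn2 (4.75 ± 0.30), Pglyrp1 (1.88 ± 0.26) and S100a8 (2.83 ± 0.48), genes of granules and cytosol of neutrophils, were among them. The abundant neutrophil genes S100a9 (0.93 ± 0.18), Camp (0.84 ± 0.20) and Ngp (0.51 ± 0.11) rose less, and Ltf (0.15 ± 0.09) was not called. Their highest group means were 5.76 for S100a9, 6.93 for Camp, 7.17 for Ngp and 7.05 for Ltf. The median of that mean over all genes was 7.89, so whether these probe sets respond was not shown.

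Some mast cell and basophil, eosinophil and erythroid genes rose in KO LK GFPhi cells, and KO replicate 3 had the highest mean for all 3 lists, which did not pass with an estimated correlation. Of 12 mast and basophil genes, 5 rose (7 adjusted over the list alone; adjusted p = 3.9e-05, and 0.0872 with an estimated correlation), including the protease genes Cpa3 (2.27 ± 0.30) of mast cells and Mcpt8 (2.10 ± 0.26) of basophils. Of 6 eosinophil genes, 4 rose (5 adjusted over the list alone; adjusted p = 0.000718, and 0.144 with an estimated correlation). Prg2 (4.61 ± 0.56), which encodes the major basic protein of eosinophil granules, was 5.65, 5.07 and 5.85 on the 3 WT arrays and 8.27, 10.18 and 11.96 on KO replicates 1, 2 and 3. Epx (3.75 ± 0.66), the eosinophil peroxidase gene, was 6.81, 8.85 and 11.66 on these KO arrays and lost the call in a fit of these 6 arrays alone. Gata1 (2.14 ± 0.45), which encodes a transcription factor of erythroid, mast and eosinophil cells, was 8.53, 9.51 and 10.99 on them and lost its call in the same way. Without replicate 3 the 4 called eosinophil genes had a median of 2.07 and stayed called. KO LK GFPhi replicate 3 had Eif2s3y at 7.74, where the other KO arrays numbered 3 had 4.01 to 4.14. Of 23 erythroid genes, 6 rose (7 adjusted over the list alone; adjusted p = 0.000755, and 0.319 with an estimated correlation), among them the stem and erythroid regulator gene Tal1 (1.09 ± 0.20). The erythroid list had means of 7.65, 7.68 and 8.39 on KO LK GFPhi replicates 1, 2 and 3 and of 7.14, 7.46 and 7.36 on the WT arrays. Its median difference was 0.47, and 0.18 without KO replicate 3 (adjusted p = 0.0191). Klf1 was 7.14, 7.62 and 9.28 on the KO arrays.

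**Figure D2:**
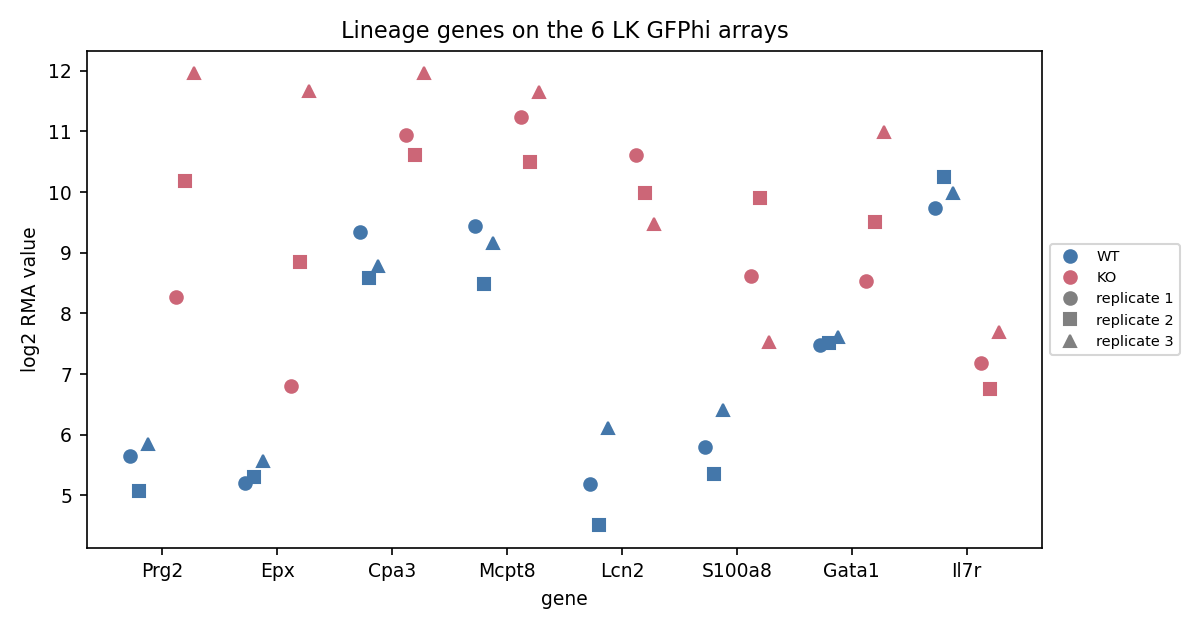
Log2 level of 8 genes on the 6 LK GFPhi arrays, WT blue and KO red, with circle, square and triangle for replicates 1, 2 and 3. KO replicate 3 was the highest for Epx (11.66), Prg2 (11.96) and Gata1 (10.99), whereas Lcn2 was 10.61, 9.99 and 9.47 in KO replicates 1, 2 and 3.

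Other genes of the LK GFPhi population that rose in KO were Cdh5 (4.72 ± 0.13), Thy1 (4.45 ± 0.29), Rhoj (4.41 ± 0.21), Apoe (4.17 ± 0.38), Mrc1 (3.68 ± 0.39) and the Ikaros family gene Ikzf2 (1.08 ± 0.20). Pkib (-3.00 ± 0.37), Cmah (-2.87 ± 0.24), Ly86 (-2.55 ± 0.30), which encodes a partner of a Toll-like receptor relative, Sdc1 (-2.37 ± 0.26) and H2-Ob (-2.16 ± 0.25) fell. Of 21 megakaryocyte genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.000242, and 0.289 with an estimated correlation), with Selp (4.03 ± 0.28) and Itga2b (2.49 ± 0.24) among the higher. Of 21 granulocyte and monocyte progenitor genes, 6 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00954, and 0.344 with an estimated correlation). The cytokine receptor gene Csf2ra (0.93 ± 0.17) rose and Irf8 (-1.32 ± 0.31), which encodes a regulator of monocytes and dendritic cells, fell. Mpo (0.09 ± 0.31) and Csf1r (-0.12 ± 0.24) were not called. The T and NK list had 5 of 19 higher (5 adjusted over the list alone; adjusted p = 0.0438, 0.0687 with the block and 0.406 with an estimated correlation). Of these, Thy1 is also known from mouse stem cells. Proliferation genes had 3 of 31 lower (3 adjusted over the list alone; adjusted p = 0.000677, and 0.381 with an estimated correlation). Interferon genes had 2 of 19 lower (3 adjusted over the list alone; adjusted p = 0.012, and 0.536 with an estimated correlation), and the sex-linked list had 0.0438, 0.0687 with the block and 0.289 with an estimated correlation. The 14 other lists did not pass (adjusted p 0.087 to 0.801). Limma called 1740 genes, 1051 higher and 689 lower in KO, of which 504 differed at least 2-fold. With the replicate block 4034 passed, with array weights 3240 and in a fit of these 6 arrays 491. Without WT replicate 1 1113 passed, without WT replicate 3 1060 and without KO replicate 3 1088.

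**Figure D3:**
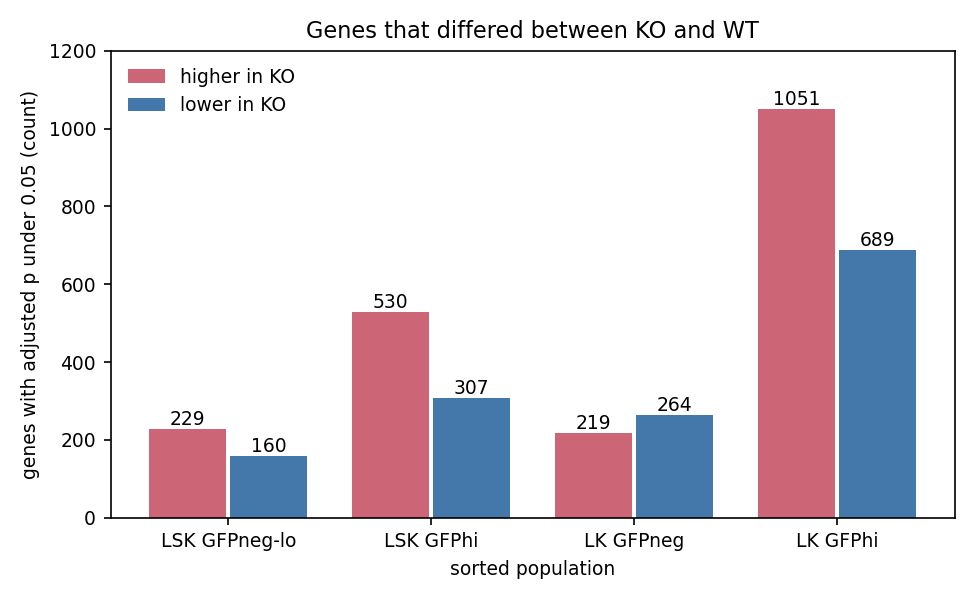
Number of genes called higher (red) and lower (blue) in KO than in WT in each population, each bar from limma at an adjusted p below 0.05 with 3 arrays per group. The bars are 229 and 160 in LSK GFPneg-lo, 530 and 307 in LSK GFPhi, 219 and 264 in LK GFPneg, and 1051 and 689 in LK GFPhi.

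In the LK GFPneg population, the lipoprotein lipase gene Lpl (4.47 ± 0.40), the small GTPase gene Ralb (3.56 ± 0.22), the T cell receptor gene segment Trgv4 (2.96 ± 0.49), Clu (2.95 ± 0.21), Bace1 (2.92 ± 0.30) and Ltbp1 (2.89 ± 0.18) rose in KO cells. Lgalsl (-2.98 ± 0.30), Marcksl1 (-2.59 ± 0.20), the interferon-induced membrane protein gene Ifitm1 (-2.40 ± 0.21), Ptprc (-2.32 ± 0.19), which encodes the pan-leukocyte phosphatase CD45, and the homeobox gene Hoxa9 (-2.30 ± 0.21) fell. Of 23 erythroid genes 0 were called, over all genes or adjusted over the list alone, and the list did not pass (adjusted p = 0.769). Gata1 (0.07 ± 0.45), the erythroid regulator gene Klf1 (0.20 ± 0.36) and the erythropoietin receptor gene Epor (0.04 ± 0.15) were not called. Of 21 megakaryocyte genes, 0 rose and 5 fell (2 and 7 adjusted over the list alone; adjusted p = 0.0332, 0.0571 with the block and 0.648 with an estimated correlation). The fallen members included the platelet protein genes Plek (-2.09 ± 0.35) and Mmrn1 (-1.80 ± 0.29). Of 23 stem cell genes, 0 rose and 3 fell (2 and 6 adjusted over the list alone; adjusted p = 0.0465, 0.0794 with the block and 0.648 with an estimated correlation). Of 19 interferon genes 3 fell (6 adjusted over the list alone; adjusted p = 3.18e-07, and 0.561 with an estimated correlation). The MHC class II list had 1 of 9 lower, H2-Ob (-2.28 ± 0.25; 1 adjusted over the list alone), and adjusted p = 0.037, 0.0571 with the block and 0.648 with an estimated correlation. The remodelling factor gene Chd3 (-1.29 ± 0.25) fell, as 1 of the 2 called among 23 genes of Ikaros and its complexes (3 adjusted over the list alone). The 22 other lists did not pass (adjusted p 0.0609 to 0.991), early lymphoid genes (0 of 19 called) and granulocyte and monocyte progenitor genes (0 of 21 called) among them. Limma called 483 genes, 219 higher and 264 lower in KO, of which 237 differed at least 2-fold. With the replicate block 888 passed, with array weights 1210, in a fit of these 6 arrays 216 and with Eif2s3y as a covariate 209. Without WT replicate 1 320 passed and without WT replicate 3 293.

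**Figure D4:**
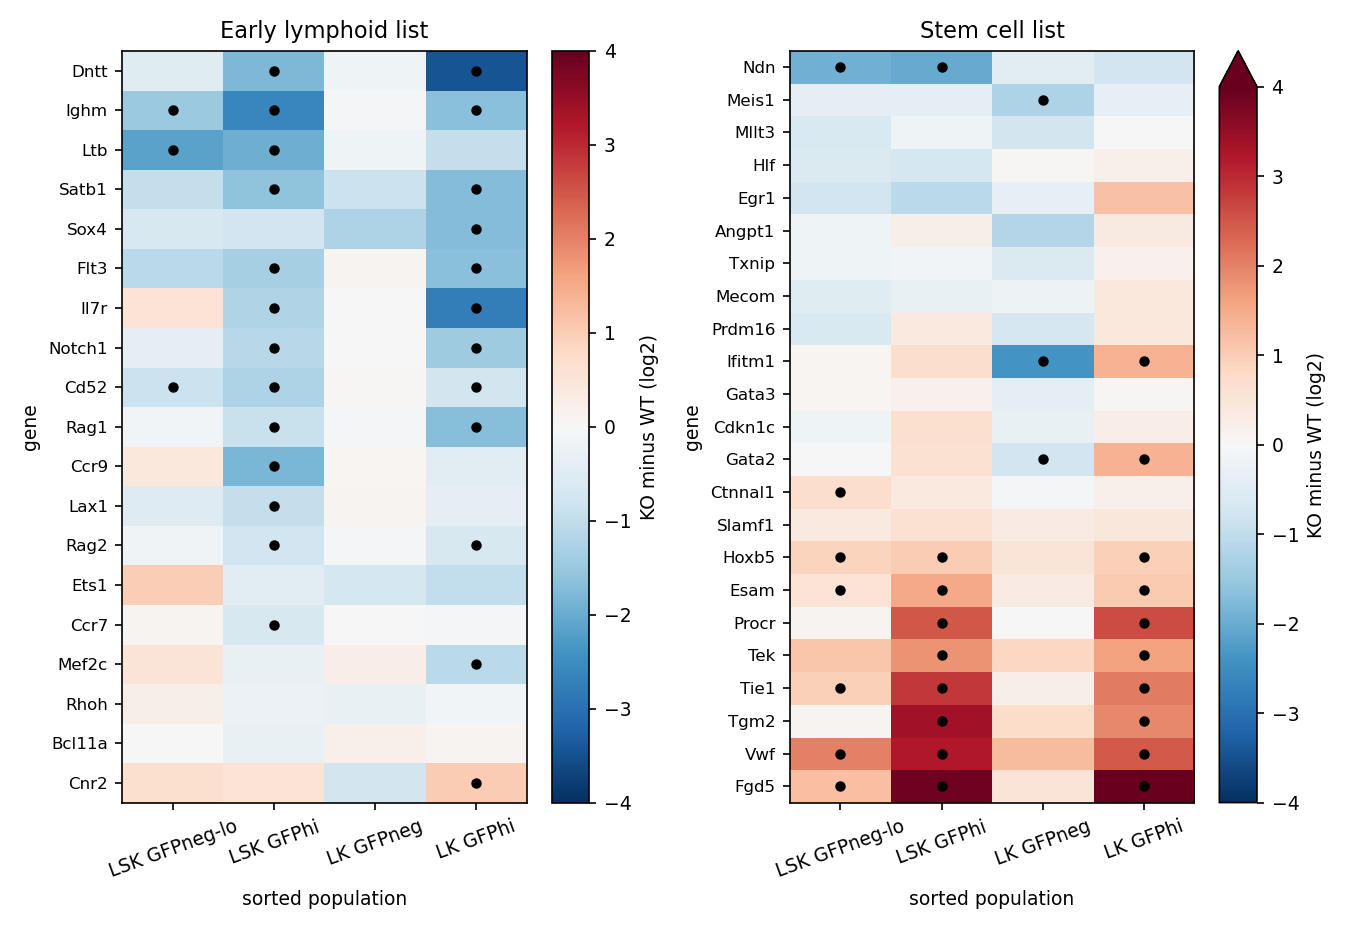
KO minus WT difference (log2, colour from -4 to 4, an arrow where a value is above 4) of each measured early lymphoid gene (19) and stem cell gene (23) in the 4 populations, with a black dot where limma called the gene. In LSK GFPhi 13 early lymphoid genes were lower and 8 stem cell genes higher, and in LK GFPhi 11 were lower and 10 higher.

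Genes called in the same direction in all 4 populations numbered 59, with 42 higher and 17 lower in KO, where 0.00464 and 0.00148 would be shared if the calls were independent. With dim genes left out the number was 63, and 35 were left at a 2-fold minimum. Deviations of 23 of the 24 arrays correlated best, on average, with the arrays of their own replicate number in other groups, so the 4 comparisons are not fully independent. Clu (3.10, 2.77, 2.95 and 3.32 in LSK GFPneg-lo, LSK GFPhi, LK GFPneg and LK GFPhi) and Spats2 (2.85, 3.06, 2.34 and 3.16) were higher throughout. So were Apoe (1.54, 3.98, 1.91 and 4.17), Pmaip1 (2.46, 3.93, 1.31 and 2.44) and Socs3 (1.95, 2.38, 1.32 and 3.45), which encodes an inhibitor of cytokine signalling. Cdh5 (4.93, 5.32, 0.53 and 4.72) was on the list with a much smaller value in LK GFPneg. The lower genes included the peptidase gene Dpp4 (-1.91, -2.00, -1.34 and -2.51), H2-Ob (-1.10, -2.42, -2.28 and -2.16), the interferon-induced GTPase gene Iigp1 (-1.74, -2.49, -1.53 and -1.74) and the cell cycle inhibitor gene Cdkn2c (-0.96, -1.12, -1.15 and -1.81). Fignl1 (-1.29, -1.94, -2.27 and -2.51) and the clone gene 1700042O10Rik (3.91, 4.01, 4.29 and 3.96) lie 27358 and 95193 bp from Ikzf1 on chromosome 11, and 1 other probe set of Fignl1 went the opposite way. Selenom, Lgalsl and Plek, named above, also lie within 10 Mb of Ikzf1. Of the 58 genes other than Ikzf1, 40 have no other probe set above the dim level. Of the 18 that have one, 10 had other probe sets that gave a median of at least 0.5 of the effect. LSK GFPhi and LK GFPhi shared 366 higher genes where 30.6 were expected by chance, and 160 lower where 11.6 were expected (r = 0.669 across genes). LSK GFPneg-lo and LSK GFPhi shared 175 higher genes (6.67 expected) and 97 lower (2.70 expected), with r = 0.716 across genes. LK GFPneg and LK GFPhi shared 85 higher genes (12.7 expected) and 58 lower (9.998 expected), while 5 and 19 genes were called in opposite directions.

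The mean KO effect over the 4 populations called 2932 genes with limma, 1775 higher and 1157 lower, of which 214 differed at least 2-fold. The fit takes the arrays of the 4 populations as independent, although same-numbered arrays correlated (residuals, median r = 0.463). Its standard errors and p-values do not allow for this. Cdh5 (3.87 ± 0.07), Gstm2 (3.19 ± 0.08), Clu (3.04 ± 0.10) and Selenom (2.93 ± 0.14) rose, as did the clone gene 1700042O10Rik (4.04 ± 0.19). Ikzf1 (-3.89 ± 0.18), Fignl1 (-2.00 ± 0.15), H2-Ob (-1.99 ± 0.13) and Dpp4 (-1.94 ± 0.16) fell. The Y-linked gene Eif2s3y was also called (-3.56). Of 19 early lymphoid genes, 0 rose and 12 fell (1 and 12 adjusted over the list alone; median -0.68, adjusted p = 6.03e-14, and 0.00373 with an estimated correlation). Of 19 interferon genes, 0 rose and 12 fell (0 and 15 adjusted over the list alone; median -0.54, adjusted p = 6.03e-14, and 0.163 with an estimated correlation). Of 21 granulocyte and monocyte progenitor genes, 10 rose and 0 fell (16 and 1 adjusted over the list alone; adjusted p = 0.000379, and 0.197 with an estimated correlation). Of 4 sex-linked genes 3 fell (3 adjusted over the list alone; median -1.42, adjusted p = 0.00527, and 0.163 with an estimated correlation). With array weights 5126 genes passed, and 850 with Eif2s3y as a covariate.

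WT lineage signatures of 150 genes were tested in KO comparisons that share no arrays with them. Same-numbered arrays of WT LSK GFPhi and LSK GFPneg-lo still correlated (residuals, r = 0.414 to 0.708), so the test is not fully independent. The lymphoid and stem signatures were the genes highest in WT LSK GFPhi and in WT LSK GFPneg-lo against both LK populations. The LSK populations were not set against each other for this, so both signatures may hold genes common to LSK cells. The myeloid and erythroid ones were those highest in WT LK GFPhi and LK GFPneg against each other. Dntt and Satb1 of the early lymphoid list were also higher in WT LK GFPhi, so the myeloid signature may hold lymphoid genes. The lymphoid signature was lower in KO LSK GFPneg-lo, with 4 genes higher and 32 lower, a median of -0.34, and adjusted p = 1.88e-24, which was 0.0472 with an estimated correlation. With 75 and 300 genes the latter was 0.0508 and 0.0565. The stem signature fell to a like extent there (10 higher and 30 lower, median -0.33). It shares WT arrays with this comparison, which favours a fall, and was not tested. A fall particular to lymphoid genes was therefore not shown. In the same population the myeloid signature had 9 genes higher and 16 lower (median -0.13, adjusted p = 1.19e-05, and 0.152 with an estimated correlation), and the erythroid signature did not pass (12 higher and 5 lower, adjusted p = 0.419). In KO LSK GFPhi the stem signature had 38 genes higher and 17 lower (median 0.19, adjusted p = 0.000731, and 0.337 with an estimated correlation). The erythroid signature there had 28 higher and 3 lower (median 0.22, adjusted p = 2.7e-08, and 0.158 with an estimated correlation). The myeloid signature there had 17 higher and 36 lower (median -0.15, adjusted p = 7.51e-05, and 0.153 with an estimated correlation). The granulocyte and monocyte progenitor list, by contrast, was higher in KO in both LSK populations with the preset correlation.

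Whether the KO effect itself differed between populations was tested by interaction contrasts. Between LSK GFPhi and LSK GFPneg-lo the effect was more positive in LSK GFPhi for Phldb2 (3.11 ± 0.41) and Lcn2 (2.95 ± 0.42), and more negative for Cmah (-2.92 ± 0.33). The stem cell list was more positive in LSK GFPhi (5 of 23 called higher, 5 adjusted over the list alone; median 0.44, adjusted p = 3.29e-15, and 0.000806 with an estimated correlation). The early lymphoid list was more negative (2 of 19 called lower, 7 adjusted over the list alone; median -0.67, adjusted p = 1.7e-15, and 0.000806 with an estimated correlation). Plasma cell genes were more negative too (2 of 8 called lower, 4 adjusted over the list alone; median -0.29, adjusted p = 1.62e-07, and 0.000756 with an estimated correlation). On the WT LSK GFPneg-lo and WT LSK GFPhi arrays the early lymphoid list had means of 8.26 to 8.51 and 9.60 to 9.66. The plasma cell list had 7.01 to 7.14 and 7.93 to 8.03. Both lists thus started lower in LSK GFPneg-lo, and the part of this in the difference was not tested. Limma called 57 genes, 36 higher and 21 lower. A fit of these groups alone called 30 and array weights 133. Without WT LSK GFPhi replicate 1 34 passed, without KO LSK GFPneg-lo replicate 2 or KO LSK GFPhi replicate 2 35, and without KO LSK GFPneg-lo replicate 3 30.

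Between LK GFPhi and LK GFPneg the effect was more positive in LK GFPhi for Lcn2 (4.65 ± 0.42), Prg2 (4.40 ± 0.79), Thy1 (4.38 ± 0.40) and Fgd5 (4.25 ± 0.37). It was more negative for Lpl (-3.95 ± 0.56), the chloride channel gene Clic5 (-3.07 ± 0.24), Pkib (-3.01 ± 0.53) and Dntt (-3.29 ± 0.67), which lost its call in a fit of these groups alone. Stem cell genes were more positive (6 of 23 called higher, 7 adjusted over the list alone; median 0.75, adjusted p = 7.69e-14, and 0.00354 with an estimated correlation). Early lymphoid genes were more negative (1 of 19 called higher and 6 lower, 1 and 9 adjusted over the list alone; median -0.79, adjusted p = 1.2e-10, and 0.007 with an estimated correlation). This list had means of 7.03 to 7.25 on the WT LK GFPneg arrays and 9.05 to 9.28 on the WT LK GFPhi arrays. It thus had less room to fall in LK GFPneg, and the part of this in the difference was not tested. Neutrophil genes were more positive (3 of 16, 7 adjusted over the list alone; adjusted p = 5.12e-06, and 0.0271 with an estimated correlation). Megakaryocyte genes (5 of 21, 9 adjusted over the list alone) and mast cell genes (3 of 12, 5 adjusted over the list alone) had adjusted p = 3.75e-10 and 5.77e-06. These were 0.0441 and 0.0449 with an estimated correlation, and 0.0525 and 0.138 when the block was added to that. Eosinophil genes had adjusted p = 8.65e-05, and 0.062 with an estimated correlation. Limma called 454 genes, 310 higher and 144 lower. With the block 907 passed, with array weights 935 and in a fit of these groups 281.

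Between LK GFPneg and LSK GFPneg-lo the effect was more positive in LK GFPneg for the secretase gene Bace1 (2.94 ± 0.43) and Clic5 (2.82 ± 0.24), and more negative for Cdh5 (-4.40 ± 0.19), Nrep (-3.56 ± 0.52) and Lgalsl (-2.93 ± 0.43). Megakaryocyte genes were more negative (6 of 21 called lower, 9 adjusted over the list alone; median -0.79, adjusted p = 6.24e-11, and 0.0974 with an estimated correlation). No list passed with an estimated correlation. Limma called 147 genes, 58 higher and 89 lower, 441 with array weights, and 92 without WT LK GFPneg replicate 3. Between LK GFPhi and LSK GFPhi the effect was more positive in LK GFPhi for Ldhb (1.82 ± 0.25), a lactate dehydrogenase gene, and more negative for the receptor gene Nrp1 (-2.64 ± 0.28) and for Raph1 (-2.20 ± 0.25). Plasma cell genes were more positive (0 of 8 called, 4 adjusted over the list alone; median 0.37, adjusted p = 7.95e-05, and 0.0101 with an estimated correlation). This list had means of 7.93 to 8.03 on the WT LSK GFPhi arrays and 7.30 to 7.49 on the WT LK GFPhi arrays. On the KO arrays it had 6.87 to 7.17 and 7.09 to 7.19. It thus started lower in LK GFPhi, and the part of this in the difference was not tested. Limma called 26 genes, 12 higher and 14 lower. A fit of these groups called 8, array weights 91 and a further quantile normalization 17. Without WT LSK GFPhi replicate 1 8 passed, without WT LK GFPhi replicates 1, 2 or 3 9, 53 and 6, without KO LSK GFPhi replicates 2 or 3 7 and 12, and without KO LK GFPhi replicates 2 or 3 12 and 43.

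The WT comparisons ask how the 4 populations differ in the presence of Ikaros. Ikzf1 itself was not called between WT LSK GFPhi and LSK GFPneg-lo (0.42, adjusted p = 0.65), between LK GFPhi and LK GFPneg (-0.26, adjusted p = 0.785), or between LK GFPneg and LSK GFPneg-lo (0.69, adjusted p = 0.184). In WT LSK GFPhi against LSK GFPneg-lo, Dntt (4.54 ± 0.48), Ighm (4.17 ± 0.36), Csf1r (3.35 ± 0.24), Jchain (3.19 ± 0.44) and the chemokine receptor gene Ccr2 (3.10 ± 0.20) were higher. The retinoid enzyme gene Aldh1a1 (-5.10 ± 0.51) and the transcription factor gene Sox6 (-4.12 ± 0.24) were lower. Stem cell genes were lower (0 of 23 higher and 20 lower, 0 and 21 adjusted over the list alone; median -1.53, adjusted p = 2.36e-42, and 4.3e-06 with an estimated correlation). Early lymphoid genes were higher (11 and 1 of 19, 12 and 1 adjusted over the list alone; median 0.80, adjusted p = 9.99e-14, and 0.00151 with an estimated correlation). Granulocyte and monocyte progenitor genes were higher (10 and 0 of 21, 11 and 0 adjusted over the list alone; median 0.77, and 0.00966 with an estimated correlation), as were plasma cell genes (4 and 0 of 8, 5 and 0 adjusted over the list alone; median 0.50, and 0.00146). Erythroid (0 and 16 of 23, 1 and 17 adjusted over the list alone; median -1.50) and megakaryocyte genes (0 and 8 of 21, 0 and 14 adjusted over the list alone; median -0.86) were lower, with 0.00171 and 0.0035 with an estimated correlation. Macrophage, dendritic and Hox genes had 0.0361 each with an estimated correlation, and 0.0952, 0.0699 and 0.0608 when the block was added to that. Limma called 822 genes, 296 higher and 526 lower, of which 374 differed at least 2-fold, and 1471 with the block.

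In WT LK GFPhi against LK GFPneg, Ctsg (6.04 ± 0.29) and Mpo (4.79 ± 0.31), which encode granule enzymes, Csf1r (5.12 ± 0.24), Satb1 (5.57 ± 0.31) and Dntt (5.78 ± 0.48) were higher. Carbonic anhydrase gene Car1 (-6.07 ± 0.48), Klf1 (-5.36 ± 0.36), Gata1 (-4.59 ± 0.45) and Epor (-3.02 ± 0.15) were lower. Granulocyte and monocyte progenitor genes were higher (20 and 0 of 21, 20 and 0 adjusted over the list alone; median 3.63, adjusted p = 1.21e-29, and 0.000192 with an estimated correlation), as were early lymphoid genes (15 and 2 of 19, 15 and 2 adjusted over the list alone; median 1.68, and 0.00316). Erythroid (0 and 19 of 23, 0 and 19 adjusted over the list alone; median -3.21) and heme synthesis genes (1 and 8 of 10, 1 and 8 adjusted over the list alone; median -1.26) were lower, with 0.00105 and 0.0143 with an estimated correlation. MHC class II genes (7 and 0 of 9, 8 and 0 adjusted over the list alone; median 1.52) had adjusted p = 9.2e-06, and 0.1 with an estimated correlation. Plasma cell genes (2 and 0 of 8, 2 and 0 adjusted over the list alone) had adjusted p = 0.0412, 0.0595 with the block and 0.1 with an estimated correlation. Limma called 3380 genes, 1816 higher and 1564 lower, of which 1503 differed at least 2-fold.

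In WT LK GFPneg against LSK GFPneg-lo, Epor (2.14 ± 0.15), Klf1 (2.41 ± 0.36) and the Rhesus blood group gene Rhd (3.13 ± 0.23) were higher. The adhesion gene Alcam (-6.04 ± 0.37), Procr (-5.11 ± 0.27), Mecom (-4.77 ± 0.25) and the MHC class II gene H2-Aa (-4.85 ± 0.47) were lower. Stem cell genes were lower (0 and 21 of 23, 0 and 21 adjusted over the list alone; median -2.04, adjusted p = 9.7e-19, and 0.0007 with an estimated correlation), as were Hox genes (0 and 9 of 10, 0 and 9 adjusted over the list alone; median -1.02, and 0.0033) and granulocyte and monocyte progenitor genes (0 and 13 of 21, 0 and 13 adjusted over the list alone; median -1.50, and 0.022). Heme synthesis genes were higher (7 and 0 of 10, 8 and 0 adjusted over the list alone; median 0.96, and 0.0243 with an estimated correlation). Erythroid genes were higher (15 and 0 of 23, 16 and 0 adjusted over the list alone; median 1.37) and early lymphoid genes lower (1 and 11 of 19, 1 and 11 adjusted over the list alone; median -1.50). These had 0.0404 and 0.0477 with an estimated correlation, and 0.0769 each when the block was added to that. Proliferation genes (20 and 0 of 31, 21 and 0 adjusted over the list alone; median 0.81) had adjusted p = 6.71e-09, and 0.137 with an estimated correlation. Limma called 4934 genes, 2368 higher and 2566 lower, of which 1973 differed at least 2-fold.

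In WT LK GFPhi against LSK GFPhi, Tifab (2.26 ± 0.23) was higher, and the lipoprotein receptor gene Vldlr (-3.28 ± 0.30), Ltb (-2.84 ± 0.34), Mecom (-2.51 ± 0.25), the stem cell transcription factor gene Hlf (-1.69 ± 0.22) and Rtp4 (-1.97 ± 0.26) were lower. Granulocyte and monocyte progenitor genes were higher (11 and 0 of 21, 13 and 0 adjusted over the list alone; median 1.05, adjusted p = 1.84e-11, and 0.0144 with an estimated correlation). Stem cell genes (0 and 10 of 23, 0 and 12 adjusted over the list alone; median -0.77) and Hox genes (0 and 4 of 10, 0 and 5 adjusted over the list alone; median -0.47) were lower, with 0.0127 and 0.0173 with an estimated correlation. Plasma cell genes were lower (0 and 2 of 8, 1 and 3 adjusted over the list alone; median -0.27, and 0.0453 with an estimated correlation, 0.059 when the block was added to that). Interferon genes (0 and 11 of 19, 0 and 16 adjusted over the list alone; median -1.10) had adjusted p = 4.84e-14, and 0.0639 with an estimated correlation. Limma called 827 genes, 367 higher and 460 lower, of which 279 differed at least 2-fold. With the block 2443 passed, with array weights 2226 and in a fit of these 6 arrays 149. Without WT LSK GFPhi replicate 1 451 passed and without replicate 2 493, and without WT LK GFPhi replicates 1, 2 or 3 305, 1708 and 352.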

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

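The tests of sex on the recurring and the stem cell genes, of linkage and probe sets, of single arrays, carry-over and gate share, and the splits made with the mean KO effect removed were chosen only after the result was seen.

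The following results were singled out because the KO effect differed between populations by the interaction test. Between LSK GFPhi and LSK GFPneg-lo 57 genes differed, with Tgm2 (3.22), Phldb2 (3.11), Lcn2 (2.95) and Mrc1 (2.85) more positive in LSK GFPhi and Slc35d3 (-3.89), Ddx4 (-3.67), Jchain (-3.25) and Cmah (-2.92) more negative. Tgm2 was 0.19 when probe sets ending in _x_at and _s_at were left out, and Mrc1 and Jchain lost the call when any of several single arrays was left out. List medians were 0.44 for stem cell, -0.67 for early lymphoid and -0.29 for plasma cell genes. Between LK GFPhi and LK GFPneg 454 genes differed, with Lcn2 (4.65), Prg2 (4.40), Thy1 (4.38) and Fgd5 (4.25) more positive and Lpl (-3.95), Dntt (-3.29), Clic5 (-3.07) and Pkib (-3.01) more negative. List medians were 0.75 for stem cell, -0.79 for early lymphoid, 0.42 for neutrophil, 0.77 for megakaryocyte and 0.77 for mast cell genes. Between LK GFPneg and LSK GFPneg-lo 147 genes differed, with Bace1 (2.94), Clic5 (2.82), Lpl (2.52) and Crim1 (2.40) more positive and Cdh5 (-4.40), Nrep (-3.56), Tmem204 (-3.52) and Lgalsl (-2.93) more negative. Between LK GFPhi and LSK GFPhi 26 genes differed, with Prg2 (4.50), Igkv8-30 (2.44), Gcsam (2.06) and Ldhb (1.82) more positive and Tmem204 (-2.90), Nrp1 (-2.64), Raph1 (-2.20) and Meg3 (-2.05) more negative. The plasma cell median was 0.37. In these comparisons Tmem204 was -0.70 and -0.25 without such probe sets, and Lpl, Crim1, Prg2, Igkv8-30, Gcsam and the second Tmem204 value lost the call with single arrays left out.

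Other splits of the arrays were counted for each result. The 6 arrays of a 3 against 3 comparison make 10 splits, too few for a share under 0.05. The real counts of 389, 837, 483 and 1740 in the KO comparisons stood beside 7, 0, 2 and 5 as the highest of the other splits, with 1 of 10 splits as large as the real one in each. Those of the WT comparisons, 822, 3380, 4934 and 827, stood beside 0, 1, 0 and 4. The real groups parted without overlap for 2897, 2999, 2522 and 4511 genes in the KO comparisons, which is 15.9, 16.5, 13.9 and 24.8% where chance gives 10%. For the 4 interactions, 9, 9, 4 and 14 of 100 splits gave as many genes, the highest 1356, 1897, 417 and 2261, several times the real counts of 57, 454, 147 and 26. Of these splits 5, 6, 3 and 11 exchanged most genotypes in 1 population, so that they carry the KO effect, a structure of the samples. For the LK interaction, whose numbers pair, 4 of the 21 splits that part as many pairs gave as many genes, the highest 1897. With the mean KO effect removed first, 1, 3, 1 and 1 of 100 splits were as large, with 1, 1408, 3 and 9 as the highest other. The split of 1408 and the next, 927, held both replicate 2 arrays together in each LK population, on opposite sides. Only 2 of 9 such splits were as large, so what gave the 1408 was not identified. Among the 21 splits that part the pairs of the LK interaction, 1 was then as large, with 4 genes as the highest other. For the mean effect 1 of 100 splits was as large as the real 2932, and the highest other gave 1319. The splits move arrays singly, whereas same-numbered arrays correlated across populations, so they do not exclude chance. Removing the mean KO effect leaves the real interaction counts unchanged and takes that effect out of the other splits. The splits chosen later therefore do not set aside the raw ones. In the raw splits the share was under 0.05 only for the interaction of LK GFPneg with LSK GFPneg-lo, and the same limit holds there. Chance is not excluded for the other 3 either.

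Genes called the same way in all 4 populations number 59. A difference in sex between KO and WT pools may have set them, since 7 KO arrays lacked Y-linked RNA, but in replicate 2, where both genotypes had that RNA, the 58 genes other than Ikzf1 had a median 0.911 of their effect in the other replicates (0.861 for the 39 genes chosen without replicate 2), where Y-linked genes had 0.0844. The 51 of them on other chromosomes do not themselves lie in DNA linked to the mutated locus. Whether linked DNA acts on genes elsewhere was not tested. Linkage stays open for the 7 on chromosome 11, of which Fignl1 and 1700042O10Rik lie within 10 Mb of Ikzf1 (Fisher's exact p = 0.0638). In the mean effect 23.3% of the genes within 10 Mb were called and 16.1% elsewhere (Fisher's exact p = 0.0306), which linkage or a local effect of the mutation may give, also for Selenom, Lgalsl and Plek. For 10 genes the other probe sets above the dim level gave a median of at least 0.5 of the effect. This argues against a variant under a single probe set as their whole cause. It does not exclude it, since probe sequences were not at hand to show which probe sets share sequence. Among the 10, Dpp4 and Socs3 also had another probe set with a ratio of 0.269 and 0.234. A variant stays open for the 8 genes with less (median over all 18, 0.580) and the 40 without such a probe set. Background strain was not tested.

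In KO LK GFPhi, some neutrophil, mast cell and basophil, and eosinophil genes were higher, and replicate 3 had the highest eosinophil and the lowest Lcn2 and S100a8 values of the KO arrays. A single KO array may have carried each group. With each KO array left out in turn, the called members kept medians of at least 1.02, 1.87 and 2.07 (from 1.16, 2.11 and 2.92). At least 6 of 8, 5 of 5 and 4 of 4 stayed called, but they were picked as called with all 3 KO arrays. The refits also share the spread of all groups, so the calls are favoured in advance. The medians show only that the rise of these members was not in 1 KO array alone. In these fits the lists had adjusted p of 0.0143 to 0.0979, 0.0200 to 0.119 and 0.0218 to 0.170 with an estimated correlation. Mature neutrophils in the gate, which a sort for Kit should remove, could bring S100a9, Ltf, Camp and Ngp, and these had a median of 0.68 beside 4.75 for Lcn2. Carry-over cannot be told apart from a change in the progenitors, because no array holds neutrophils to show what these probe sets read in them, and a change in the composition of the gate by loss of Ikaros was not tested.

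Stem cell genes were higher in KO LSK GFPhi. Cells of the GFPneg-lo kind in the GFPhi gate may give this, and they cannot be told apart from a change within cells, because gene sets disagree on the share of such cells that would be needed. As a percent of the distance from WT GFPhi to KO GFPneg-lo on the linear scale, that share was a median 17.5% for 20 stem cell genes, 8 of them called higher, and 1.35% for 16 erythroid genes (one-sided permutation p = 0.00579). It was 21.7% for 7 megakaryocyte genes (one-sided permutation p = 0.669), 9.79% for 103 genes of the erythroid signature (p = 0.119) and 31.2% for 490 other genes higher in WT GFPneg-lo (p = 0.898). Quartiles were 4.87 and 36.5% for the stem cell genes and -2.12 and 10.4% for the erythroid genes. The permutations moved genes between sets, so their p-values take genes as independent and do not measure the spread between arrays. The stem cell list was taken up because it rose in this comparison, which favours a larger share. All sets were picked as lower in WT GFPhi than in WT GFPneg-lo, and WT GFPhi is also the start of the distance. The 8 called stem cell genes ran from 12.2% (Vwf) to 114% (Fgd5), whereas Hlf, not called, had -107%. Sex of the pools is argued against by replicate 2, where the 8 stem cell genes called without replicate 2 had a median 1.13 of their effect in the other replicates, and strain was not tested.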

How the results depend on the processing

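The covariate of Eif2s3y level was chosen after the data were seen and is partly confounded with genotype. Where a call or count moved, the cause was not tested, except that a fold minimum lowers counts by construction. Results are ordered as KO in LSK GFPneg-lo, LSK GFPhi, LK GFPneg and LK GFPhi, the WT comparisons of LSK GFPhi with GFPneg-lo, LK GFPhi with GFPneg, LK GFPneg with LSK GFPneg-lo and LK GFPhi with LSK GFPhi, the interactions LSK, LK, GFPneg and GFPhi, and the mean.

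In a fit of the compared groups alone, KO counts were 199 in LSK GFPneg-lo, 216 in LK GFPneg and 491 in LK GFPhi, 149 for WT LK GFPhi against LSK GFPhi, and 30, 281 and 8 for the LSK, LK and GFPhi interactions, and the mean effect has no such fit. With the replicate block the KO counts were 844, 1367, 888 and 4034, WT LSK 1471, WT GFPhi 2443, the interactions 97, 907, 307 and 103, and the mean 4816. All genes called without the block were called with it. In comparisons whose numbers do not pair, the block moved the interferon list of KO LSK GFPhi to 0.0585 with an estimated correlation, the stroma list of the GFPneg interaction to 0.071 and the mast list of the GFPhi interaction to 0.0986. Beside these and the values in the report, the block ended no other call, and 11 more named genes passed with it. Array weights gave 1120, 1288, 1210 and 3240 for KO, 2226 for WT GFPhi, 133, 935, 441 and 91 for the interactions and 5126 for the mean. A further quantile normalization gave 17 for the GFPhi interaction. A 2-fold minimum left 172, 384, 237 and 504, then 374, 1503, 1973 and 279, 214 for the mean and 35 of the genes shared by all 4 populations. The Eif2s3y covariate gave 210, 499 and 209 for KO in LSK GFPneg-lo, LSK GFPhi and LK GFPneg, and 850 for the mean. With it the immediate early list of KO LK GFPneg turned direction (adjusted p = 0.00367).

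Leaving out 1 array gave 232 to 357, 570 to 715, 293 to 468 and 1060 to 2087 for KO, 560 to 746, 2701 to 3123, 3743 to 4471 and 305 to 1708 for WT, 30 to 69, 361 to 499, 92 to 139 and 6 to 53 for the interactions, and 2509 to 3153 for the mean. The arrays that moved a count over 1.5 times are named in the report.

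Of 338 list tests 131 passed, and 42 with an estimated correlation. Signatures then had 0.152, 0.153, 0.158 and 0.337. Robust eBayes does not apply to camera. Of 441 calls of named genes, 441 held with the block, 439 with trend and robust, 439 with array weights, 435 with centring, 429 with quantile normalization and 408 with the covariate. In a fit of the groups alone 342 of 433 held, and without _x_at and _s_at probe sets 403 of 423. Without those probe sets 3 turned direction: Hoxa5 in KO LK GFPhi (-0.22), Tgm2 in WT LSK (0.069) and Ccr9 in WT LK (-0.012). Of 2982 calls with 1 array left out, 2672 held. Genes near background are measured with less precision, and leaving out dim genes ended 0 of the 430 calls of genes that were kept and 16 of 131 list calls.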

Other observations

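Interferon response genes had medians of -0.67, -0.84, -0.45 and -0.24 in KO LSK GFPneg-lo, LSK GFPhi, LK GFPneg and LK GFPhi, and passed camera in all 4, though with an estimated correlation only in LSK GFPhi (0.0364, and 0.0585 when the block was added to that). WT replicate 3 had the highest WT mean of these genes in every population (9.49, 9.78, 8.35 and 8.27), and without it the list did not pass in LK GFPhi (adjusted p = 0.0695). B lineage genes passed in 1 of the 4 KO comparisons, and Notch, ribosomal protein, Hox, Ikaros complex and Ikzf1 neighbour genes in 0. Among lists that did not pass, the median, the mean and the test differed in sign for Notch genes in LSK GFPneg-lo, LSK GFPhi and LK GFPhi, for plasma cell genes in LSK GFPneg-lo and LK GFPhi, for Ikaros complex genes in all but LK GFPhi, and for Ikzf1 neighbours in all 4. The same held for Hox genes in LSK GFPneg-lo, for mast, eosinophil, proliferation and ribosomal protein genes in LK GFPneg, and for B lineage and dendritic genes in LK GFPhi.

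WT Ikzf1 RNA followed the GFP gate in the LSK sort, where GFPhi was above GFPneg-lo in each replicate number (11.72 and 11.36, 11.41 and 11.09, 11.59 and 10.99). In the LK sort it did not, since GFPneg cells had the highest mean of the 4 (11.84 ± 0.13, SD, n = 3) and GFPhi 11.58 ± 0.13. Neither difference was called, with a standard error that also counts the spread of the KO arrays. The 129 genes within 10 Mb of Ikzf1 were lower in WT LSK GFPhi than in LSK GFPneg-lo (0 higher and 8 lower, 0 and 9 adjusted over the list alone; adjusted p = 0.0243, and 0.0441 with an estimated correlation). That call was lost in a fit of these groups alone, with dim genes left out and after a further quantile normalization. They did not pass in any KO comparison (adjusted p from 0.0609). No explanation was tested.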
